A study of Arabidopsis thaliana with 30 samples.

How the data were processed

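Transcript levels in leaves of 21-day-old Arabidopsis thaliana plants were measured on Affymetrix ATH1 arrays, which carry short probes for most genes of the reference accession Columbia (Col-0). There were 30 arrays in 10 groups of 3: Col-0, a WRKY40 knockout, a WRKY40 overexpressor, a WRKY63 knockout and a WRKY63 overexpressor, each untreated and after 1 h of high light at 1000 µE per square metre per second. Groups and replicate numbers were taken from the sample titles. The design text of the series speaks of WRKY60 where the series title and all sample labels say WRKY63, and the labels were followed. The labels do not say whether replicates came from separate plants or cultures, so the p-values measure the spread between these samples, which may be technical.

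The deposited values are 1 signal intensity per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes; its version and settings are not given in the sources used here. On every array the deposited intensity had a mean between 500 and 500.1 after the lowest and highest 2 percent of probe sets were left out, so the arrays had been scaled to a common mean. No detection calls accompanied the values used here, so no rule on background could be applied, and low signals were limited by a filter instead. The number of arrays, 3 per group, limits the precision of each value. No arrays held identical values. Within a group the correlation of log2 signals between arrays ran from 0.936 to 0.979.

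The values were analysed in R 4.3.3 with limma 3.58.1. Of the 22810 probe sets, 64 control probe sets were left out. A pseudocount of 1 was added, log2 was taken, and the 15922 probe sets with a mean log2 signal at or above the 30th percentile, a signal of 46.7, were kept. A model with a mean for each of the 10 groups was fitted to all 30 arrays, with limma's empirical Bayes moderation and a trend of variance on signal. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Fold changes are on the log2(signal + 1) scale, which understates changes of dim probe sets and depends on the pseudocount there. Errors of log2 changes are limma's standard errors, and errors of signals are standard deviations (SD).

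The 19 comparisons were high light against untreated in each genotype, each line against Col-0 in each light, the difference of each line's response to high light from that of Col-0 (interaction), and each overexpressor against its knockout over both lights. These choices, the gene lists named as fixed and the rule for named genes were set before the data were examined. The rule took the 6 largest rises and 6 largest falls among called probe sets that name 1 gene and whose groups do not overlap, and up to 2 rising and 2 falling called members of each fixed list; in the other comparisons it took 3 and 3. An interaction has no pair of groups to compare for overlap, so that part of the rule was not applied there, and in the comparisons of overexpressor with knockout it was applied within each light. WRKY40, WRKY63, WRKY60, WRKY18, AOX1A, BCS1, NDB2 and AT2G21640 (UPOX) were to be given in every comparison of a line with Col-0 and for high light in Col-0, but the first 6 are not named by the annotation used here. The knockouts and overexpressors could therefore not be checked on their own transcripts.

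Probe sets were named from the platform annotation, which can be old. Of the 22746 probe sets that are not controls, 13513 name 1 gene, 503 name several and 8730 are unnamed here; among the probe sets kept the numbers are 8768, 323 and 6831. Gene order along the chromosomes came from the TAIR10.1 gene table and was used only to find neighbouring genes. Of 108 named probe sets, 1 (AT5G37230) is of the type that can bind transcripts of several genes.

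Gene lists were compared with all other kept probe sets by limma's camera with a preset correlation of 0.01, and again with a correlation estimated from the arrays. Of 251 members of the 15 fixed lists, 32 had a named probe set, and only the heat shock list kept the 5 probe sets needed for a test. A further 17 lists were drawn up after the annotation was read and before any expression test. In the resulting 18 lists, 65 tests were called over the 19 comparisons with the preset correlation. With an estimated correlation the calls that hold are those of both heat shock lists after high light in every genotype, mitochondrion-encoded genes after high light in the WRKY63 overexpressor, and nuclear photosynthesis genes in the interaction of the WRKY63 knockout.

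On simulated data with 3 arrays per group and the 15922 probe sets, the steps recovered 67% of planted log2 changes of 1 and 94% of planted changes of 2 in high light in Col-0, with 5 false calls. For the interaction of the WRKY40 knockout the recovered shares were 46% and 85%, with 4 false calls. For the WRKY63 knockout in high light they were 69% and 94%, with 12 false calls. The alternatives tried were a pseudocount of 16, no filter, a filter at the 50th percentile, quantile normalization, a replicate block, no variance trend, a fit to only the arrays compared, and leaving out each array in turn. A fit to the 28 arrays without high ratios of actin 3' to 5' probe sets was added after the data were seen.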

Results

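Leaf transcripts were measured in Col-0 and in plants lacking or overexpressing WRKY40 or WRKY63, transcription factors of the plant-specific WRKY family, with and without 1 h of high light. Each of the 10 groups held 3 arrays. The scaled arrays had median signals of 168.9 to 187.2 without treatment and 148.2 to 164.8 after high light. The first principal component held 54.5% of the variance and the second 11%. The log2 ratio of actin 3' to 5' probe sets, a sign of RNA quality, had a median of 1.65 over the arrays, with 2.35 in Col-0 untreated replicate 2 and 2.32 in WRKY63 overexpressor high light replicate 3.

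The response of Col-0 to high light is the reference for every line. The small heat shock proteins AT1G53540 and AT2G29500, chaperones that bind unfolded proteins, rose from signals of 29.7 ± 23.1 and 49.9 ± 5.63 to 31100 ± 1850 and 33300 ± 2110 (SD, n = 3), log2 changes of 10.54 ± 0.70 and 9.36 ± 0.35 (SE). AT1G52560, another small heat shock protein, rose from 1.96 ± 1.7 to 10100 ± 1490, and the co-chaperone Hop3 rose from 45.4 ± 34.1 to 14500 ± 1150. Of the 19 members of the fixed heat shock list 6 had a kept named probe set, and 6 of 6 were higher, also when adjusted over the list alone. Their median log2 change was 8.20 (camera adjusted p = 3.5e-14). In a wider chaperone list 14 of 18 probe sets rose and 2 fell, among them Fes1B with -2.25.

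Mitochondrial stress transcripts rose in Col-0 as well. Of the 19 members of the fixed list only 4 had a named probe set that passed the filter. All 4 were called, also when adjusted over the list alone. AT2G21640, a mitochondrial stress marker, rose from 298 ± 162 to 3770 ± 767 (log2 3.78 ± 0.29, limma adjusted p = 7.69e-11). NDB2, an alternative NAD(P)H dehydrogenase of the mitochondrial inner membrane, rose from 235 ± 24.7 to 788 ± 148 (log2 1.73 ± 0.21, adjusted p = 2.17e-07), and the mitochondrial small heat shock protein AT5G51440 rose by 8.30 ± 0.29. AT5G09570 rose by 1.38 ± 0.43. The plot of mitochondrial stress transcripts shows these levels array by array.

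**Figure D1:**
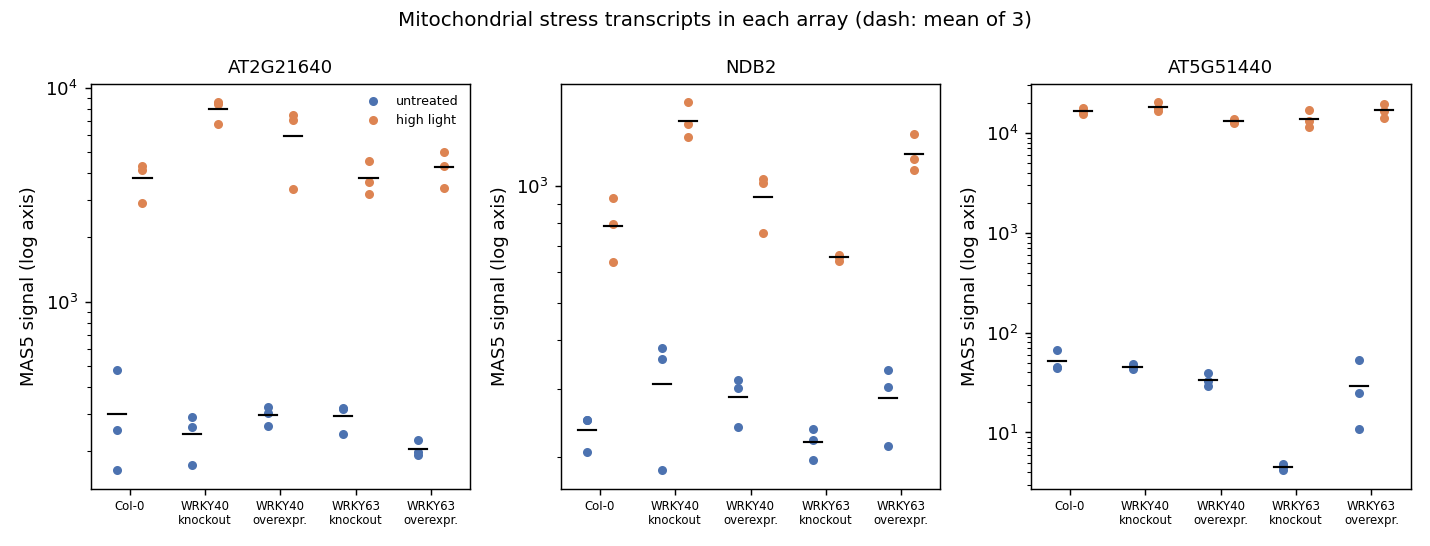
MAS5 signal (log axis) of AT2G21640, NDB2 and AT5G51440 in each array, untreated and after high light, for Col-0 and the 4 lines; points are arrays and dashes are means of 3. In Col-0 the mean of NDB2 rose from 235 to 788, and in the WRKY40 knockout after high light it was 1470.

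Further members of the fixed lists changed in Col-0. The zinc finger gene STZ rose by 3.59 ± 1.04 on the log2 scale (adjusted p = 0.00665), the dehydrin COR47 rose by 2.05 ± 0.20 and the glutaredoxin GRX480 by 1.58 ± 0.43. COR15A rose by 1.14 ± 0.41 (adjusted p = 0.0255), a call that ended with quantile normalization (1.02, adjusted p = 0.0513) and without Col-0 untreated replicate 1 (1.08), Col-0 untreated replicate 2 (0.84) or Col-0 high light replicate 3 (1.01). The light-harvesting gene LHCB4.2 fell by 0.50 ± 0.10, the lycopene cyclase gene LYC by 0.28 ± 0.10 (adjusted p = 0.0202), BCAT4 of glucosinolate synthesis by 0.84 ± 0.17, SAG101 by 0.99 ± 0.31 and the root marker PYK10 by 1.82 ± 0.50. The call of LYC ended with quantile normalization (adjusted p = 0.0526) and on only the arrays compared (adjusted p = 0.11). It also ended without Col-0 untreated replicate 1 (-0.27) or 3 (-0.24) or Col-0 high light replicate 2 (-0.26) or 3 (-0.23). The largest falls by the rule were AT4G33980 (-4.94 ± 0.73), AT1G19960 (-4.73 ± 0.31), AT3G62550 (-4.35 ± 0.75), AT1G07050 (-4.21 ± 0.25), AT3G18250 (-4.20 ± 0.86) and the cell wall expansin EXPA8 (-4.12 ± 0.34).

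In all, limma called 6995 probe sets for high light in Col-0, 2379 higher and 4616 lower, of which 1216 and 1643 changed at least 2-fold. The median log2 change of all probe sets was -0.18, and -0.08 with quantile normalization, so part of the excess of falls moves with the scaling. Transcripts encoded in the mitochondrial genome had 11 of 18 probe sets higher, such as cox2 (2.88 ± 0.24) and nad6 (2.77 ± 0.70), with a median of 1.22 (camera adjusted p = 1.1e-04; adjusted p = 0.14 with an estimated correlation). With the filter at the 50th percentile that median was 0.11 (adjusted p = 0.236).

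The same treatment was compared within each line. AT1G53540 rose by 9.70 ± 0.70 in the WRKY40 knockout, 9.84 ± 0.70 in the WRKY40 overexpressor, 9.81 ± 0.70 in the WRKY63 knockout and 9.90 ± 0.70 in the WRKY63 overexpressor. The heat shock list had 6 of 6 members higher in each line, with medians of 8.30, 7.59, 7.65 and 7.93. The cold-regulated gene COR27 fell by 4.47 ± 0.74, 4.50 ± 0.74 and 4.81 ± 0.74 in the WRKY40 knockout, the WRKY40 overexpressor and the WRKY63 knockout, and its change was -4.43 in the WRKY63 overexpressor. AT1G19960 had -4.37, -3.94, -4.39 and -5.38 in the 4 lines in that order. AT3G12870 fell by 4.46 ± 0.46 in the WRKY63 overexpressor against -2.21 in Col-0, a difference that was not called (-2.25 ± 0.65, adjusted p = 0.13). Tubulins, the subunits of microtubules, had 6 of 7 probe sets lower in the first 3 lines and 7 of 7 in the WRKY63 overexpressor (camera adjusted p = 0.0013, 0.0034, 0.0098 and 0.0059; adjusted p = 0.098, 0.14, 0.18 and 0.14 with an estimated correlation). Mitochondrion-encoded genes had 13 of 18 probe sets higher in the WRKY63 overexpressor, with a median of 1.35 (camera adjusted p = 1.4e-06; adjusted p = 0.045 with an estimated correlation). With the filter at the 50th percentile that median was 0.73 (adjusted p = 0.0657).

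Calls for high light numbered 6898 in the WRKY40 knockout (2284 higher), 6507 in the WRKY40 overexpressor (2258 higher), 7399 in the WRKY63 knockout (2253 higher) and 8152 in the WRKY63 overexpressor (2532 higher). Of the 11530 probe sets called in any genotype, 3763 were called in all 5 in the same direction, 1338 higher and 2425 lower, and 160 were called in opposite directions. The median change of all probe sets was -0.20, -0.17, -0.22 and -0.25 in the lines and -0.10, -0.11, -0.08 and -0.12 with quantile normalization. In the WRKY63 knockout the share of calls that were higher was 30.5%, and 42.3% with quantile normalization.

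**Figure D2:**
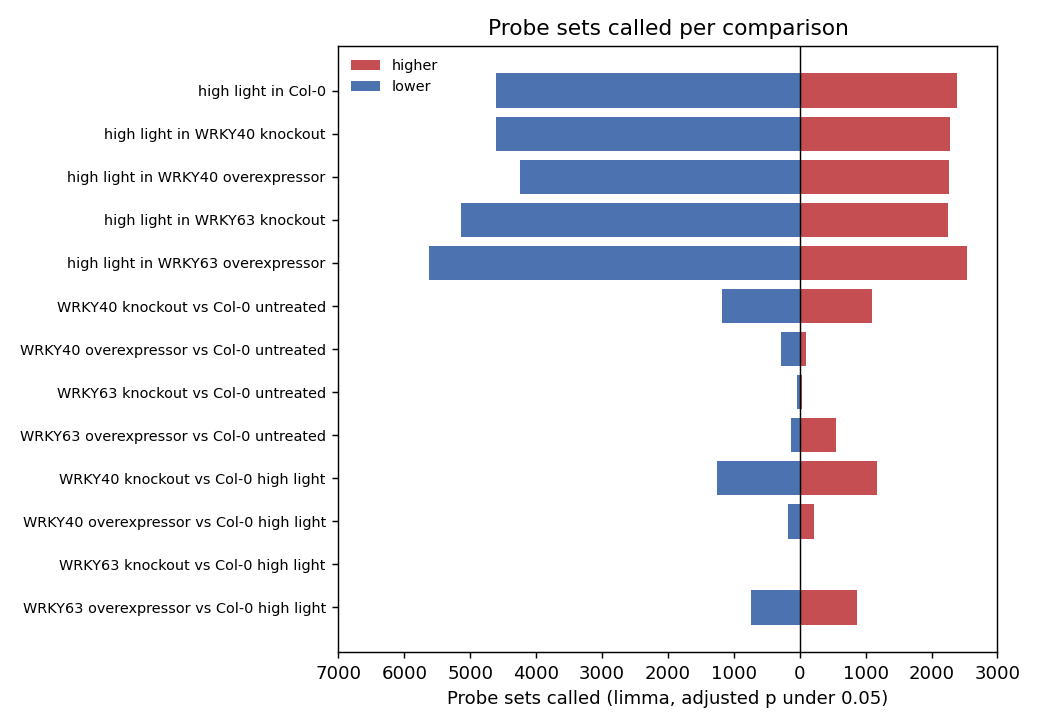
Number of probe sets called by limma as higher (red, right) or lower (blue, left) in the 13 comparisons of 2 groups; the linear axis counts probe sets from 0 in both directions. High light gave 6507 to 8152 calls, and the lines against Col-0 gave 4 to 2426.

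The next comparisons ask how the lines differ from Col-0 without treatment. In the WRKY40 knockout AOP3, a dioxygenase of glucosinolate synthesis, stood at 8490 ± 497 against 32.6 ± 8.59 in Col-0 (SD, n = 3), a log2 difference of 8.01 ± 0.67 (adjusted p = 1.59e-09). The signal of AT1G66100 was almost lost, at 13.2 ± 7.59 against 6540 ± 4590, as were those of AT2G25510 (136 ± 33.5 against 31500 ± 5200), AT3G22240 (253 ± 53.8 against 30800 ± 3570), AT2G25450 (32.2 ± 19.3 against 4940 ± 1410), AT1G76960 (3.95 ± 1.47 against 1390 ± 568) and AT5G45500 (18.8 ± 14.9 against 1080 ± 409). AT3G59845, AT5G15360, AT1G50290, AT3G48640 and AT1G48750 were higher by log2 differences of 4.80 to 3.05. COR15A, a cold-induced chloroplast protein, was lower by -2.03 ± 0.41 while COR47 was higher by 0.96 ± 0.20. LHCB4.2 was lower by -0.80 ± 0.10 and AT2G29500 by -1.28 ± 0.35 (adjusted p = 0.0144), the latter at signals of 20.2 and 49.9 and without a call on leaving out WRKY40 knockout untreated replicate 2 (-1.15, adjusted p = 0.0594) or on only the arrays compared (adjusted p = 0.153).

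Limma called 2271 probe sets in this comparison, 1092 higher and 1179 lower, of which 346 and 525 differed at least 2-fold. A fit to only these 6 arrays called 1373. Some of these differences may come from chromosome segments of another accession rather than from loss of WRKY40, as weighed further below. The probes are made for Col-0, so in such a segment a lower signal need not be a lower transcript level. This was not tested. NDB2 (0.32 ± 0.21, adjusted p = 0.346) and AT2G21640 (-0.20 ± 0.29, adjusted p = 0.73) were not called. Without WRKY40 knockout untreated replicate 2, NDB2 had a difference of 0.65 (adjusted p = 0.0188). Among UDP-glycosyltransferases, enzymes that attach sugars to small molecules, 6 of 26 were lower, among them UGT84A4 by -1.03 ± 0.21 and UGT76C1 by -1.02 ± 0.25 (camera adjusted p = 0.019; adjusted p = 0.29 with an estimated correlation). The list lost its call with no filter (median -0.18, adjusted p = 0.0718) and without Col-0 untreated replicate 2 (median -0.30, adjusted p = 0.0722).

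The WRKY40 overexpressor differed less from untreated Col-0. AT5G12940 was lower, at 38.9 ± 30.6 against 517 ± 175 (-4.05 ± 0.55, adjusted p = 5.16e-05), and so were ZCF37 (11 ± 4.09 against 228 ± 174), AT4G16260 (18.1 ± 9.64 against 439 ± 399) and the auxin-responsive gene IAA29 (28.7 ± 25.6 against 264 ± 111), whose difference was -2.80 (adjusted p = 0.0637) without WRKY40 overexpressor untreated replicate 1. AT3G28270 was higher, at 1190 ± 547 against 192 ± 3.91 (2.49 ± 0.38, adjusted p = 2.47e-04), as were AT1G67330 (2.13 ± 0.26), AT3G15720 (2.01 ± 0.40) and GLC (1.91 ± 0.36). The defensin PDF1.2 was lower by -3.07 ± 0.76 (adjusted p = 0.0262), but its Col-0 signal was 2200 ± 3390 and without Col-0 untreated replicate 2, an array with a high actin ratio, the difference was -1.51 (adjusted p = 0.217). WRKY6, linked to leaf senescence, was lower by -2.05 ± 0.52 (adjusted p = 0.0298), and -1.86 (adjusted p = 0.161) without that array; it also lost its call without Col-0 untreated replicate 3 (-2.09) or WRKY40 overexpressor untreated replicate 2 (-1.71) or 3 (-1.72), as did PDF1.2 without WRKY40 overexpressor untreated replicate 1 (-2.97), 2 (-2.99) or 3 (-3.25). On only the arrays compared neither was called (adjusted p = 0.223 for WRKY6 and 0.251 for PDF1.2), and with a pseudocount of 16 WRKY6 had -1.33 (adjusted p = 0.0558).

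Limma called 390 probe sets here, 100 higher and 290 lower. The count was 218 without Col-0 untreated replicate 2, 237 and 230 without WRKY40 overexpressor untreated replicates 2 and 3, 239 on only the arrays compared and 247 on the 28 arrays. Of the 13 named genes called, 6 lost the call when 1 array was left out. NDB2 (0.27 ± 0.21) and AT2G21640 (0.12 ± 0.29) were not called.

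In the untreated WRKY63 knockout the mitochondrial small heat shock protein AT5G51440 was lower, at 4.52 ± 0.352 against 52.5 ± 13.1 (-3.25 ± 0.29, adjusted p = 5.3e-07), a difference between dim signals that was -1.72 with a pseudocount of 16. AT4G39670 (-3.36 ± 0.47, and -2.10 with a pseudocount of 16) and AT1G62760 (-2.71 ± 0.39) were lower. AT1G72230 was higher, at 1220 ± 190 against 339 ± 66.6 (1.86 ± 0.28, adjusted p = 0.00183), and 1.69 (adjusted p = 0.0567) on the 28 arrays without high actin ratios. AT4G21650 (2.09 ± 0.37) and the wax ester synthase gene WSD1 (1.77 ± 0.32) were higher, with 1.91 (adjusted p = 0.0714) and 1.25 (adjusted p = 0.0745) when Col-0 untreated replicate 2 was left out, and 1.93 and 1.68 without a call when WRKY63 knockout untreated replicate 2 was. PDF1.2 was lower by -3.65 ± 0.76, and by -2.09 (adjusted p = 0.106) without Col-0 untreated replicate 2; without WRKY63 knockout untreated replicate 1 (-3.97), 2 (-3.32) or 3 (-3.66) it was not called either. On only the arrays compared AT5G51440, AT4G39670 and AT1G62760 were not called (adjusted p = 0.163, 0.166 and 0.106). Neither were WSD1 (adjusted p = 0.132) and PDF1.2 (adjusted p = 0.241).

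Limma called 80 probe sets, 36 higher and 44 lower. The count was 6 without Col-0 untreated replicate 2, 25 and 21 without WRKY63 knockout untreated replicates 1 and 2, 17 on only the arrays compared and 4 on the 28 arrays without high actin ratios. Of 12 named genes called, 8 lost the call when 1 array was left out. NDB2 (-0.11 ± 0.21) and AT2G21640 (0.10 ± 0.29) were not called.

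In the untreated WRKY63 overexpressor the cytochrome P450 gene CYP71B23 was at 2600 ± 117 against 227 ± 112 (3.66 ± 0.58, adjusted p = 2.73e-04), the pectin methylesterase gene ATPMEPCRB at 1460 ± 216 against 177 ± 11.7 (3.03 ± 0.33), GRX480 at 913 ± 94.3 against 151 ± 86.2 (2.75 ± 0.43) and WRKY53, a regulator of leaf senescence, at 681 ± 153 against 211 ± 121 (1.82 ± 0.42, adjusted p = 0.0098). The small heat shock protein AT1G52560 was at 223 ± 47.5 against 1.96 ± 1.7 (6.36, and 3.72 with a pseudocount of 16), and AT4G39830 was higher by 3.31 ± 0.55. AT5G41620 (18.6 ± 13.3 against 82.2 ± 19.8) and AT2G29500 (20.7 ± 13.6 against 49.9 ± 5.63) were lower, by -2.35 and -1.54. With a pseudocount of 16 these were -1.56 and -0.92. On only the arrays compared neither was called (adjusted p = 0.0865 and 0.322). AT2G29500 had -0.78 without WRKY63 overexpressor untreated replicate 2. WRKY53 had 1.44 (adjusted p = 0.0844) without Col-0 untreated replicate 1 and 1.64 (adjusted p = 0.0536) without WRKY63 overexpressor untreated replicate 2.

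Limma called 678 probe sets, 545 higher and 133 lower. The count was 437 without Col-0 untreated replicate 1 and 308 without WRKY63 overexpressor untreated replicate 1. Of 16 named genes called, 9 lost the call when 1 array was left out. NDB2 (0.25 ± 0.21) and AT2G21640 (-0.40 ± 0.29) were not called. Plastid-encoded ribosomal and polymerase genes had 0 of 19 members called and a median of -0.48 (camera adjusted p = 2e-04; adjusted p = 0.58 with an estimated correlation).

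Nuclear photosynthesis genes lay slightly below Col-0 in all 4 untreated lines, which share the Col-0 arrays. Their median was -0.11 in the WRKY40 knockout with 4 of 30 members lower, -0.14 in the WRKY40 overexpressor with 0, -0.14 in the WRKY63 knockout with 0 and -0.15 in the WRKY63 overexpressor with 1. The camera adjusted p was 0.019, 5.6e-04, 2.7e-06 and 3.2e-04 in that order, and the adjusted p was 0.59, 0.67, 0.19 and 0.58 with an estimated correlation. With quantile normalization no line kept the call (medians -0.02, -0.07, -0.08 and -0.11; adjusted p = 0.309, 0.0642, 0.0521 and 0.112). The WRKY40 overexpressor also lost it without its untreated replicate 2 (-0.10, adjusted p = 0.142). The WRKY40 knockout lost it without its untreated replicate 1 (-0.05) and without Col-0 untreated replicate 1 (-0.12) or 2 (-0.07).

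After high light the WRKY40 knockout had higher mitochondrial stress transcripts than Col-0. AT2G21640 was at 7950 ± 995 against 3770 ± 767 (1.09 ± 0.29, adjusted p = 0.0112), NDB2 at 1470 ± 157 against 788 ± 148 (0.91 ± 0.21, adjusted p = 0.00292) and AT5G09570 at 577 ± 37.2 against 180 ± 3.85 (1.67 ± 0.43, adjusted p = 0.00768). These are 3 of the 4 members, of 19 on the fixed list, with a kept named probe set, also 3 when adjusted over the list alone. The remaining member of the 4, AT5G51440, had 0.14 ± 0.29. Without Col-0 high light replicate 1, AT2G21640 had 0.91 (adjusted p = 0.0664). Whether their response to high light itself differed from Col-0 was tested as an interaction and not called, with 1.29 ± 0.41 (adjusted p = 0.17) for AT2G21640, 0.59 ± 0.30 (adjusted p = 0.45) for NDB2 and 0.50 ± 0.60 (adjusted p = 0.82) for AT5G09570. Whether the higher levels come from loss of WRKY40 or from chromosome segments of another accession was not tested.

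AOP3 remained far above Col-0 in the WRKY40 knockout after high light, at 3200 ± 78.5 against 49.4 ± 13.7 (6.03 ± 0.67). AT1G02700 was at 2970 ± 152 against 217 (3.77 ± 0.36), AT3G48640 at 1280 ± 417 against 48.9 ± 20.2 and AT5G55450 at 2730 ± 1250 against 209 ± 17.1. AT1G66100 was at 2.04 ± 0.322 against 5250 ± 422 (-10.75 ± 0.45), AT2G25510 at 78.4 ± 25.0 against 20800 ± 3700, and AT2G01090 at 19.3 ± 13.0 against 948 ± 51.3. LHCB4.3, an antenna protein gene, was higher by 1.03 ± 0.22 and LHCB4.2 was lower by -0.71 ± 0.10, while COR15A was lower by -2.56 ± 0.41. The anthocyanin glycosyltransferase AT4G14090 was lower by -1.74 ± 0.58 (adjusted p = 0.0422), the only 1 of 3 flavonoid members called, with 3 lower when adjusted over the list alone; its call ended with no filter (adjusted p = 0.0556), quantile normalization (adjusted p = 0.0518) and no variance trend (adjusted p = 0.0561). It also ended without Col-0 high light replicate 2 (-1.51) or 3 (-1.69) or WRKY40 knockout high light replicate 1 (-1.54), 2 (-1.87) or 3 (-1.81).

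Limma called 2426 probe sets, 1175 higher and 1251 lower. In this line 1098 probe sets were called in both lights in the same direction and 19 in opposite directions, where 173.2 in the same direction would be expected of independent lists; 431 of the 1098 differed at least 2-fold in both lights, 113 higher and 318 lower.

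In the WRKY40 overexpressor after high light AT1G67330 was higher, at 483 ± 37.1 against 80 ± 22.2 (2.62 ± 0.26, adjusted p = 1.41e-06), as were AT5G64120 (467 ± 53.8 against 94.8 ± 16.0) and AT3G01750 (2.91 ± 0.52; 1.64 with a pseudocount of 16, and adjusted p = 0.108 on only the arrays compared). AT2G29340 was lower, at 139 ± 14.7 against 672 ± 86.9 (-2.26 ± 0.18, adjusted p = 2.37e-08), as were TRY, a repressor of leaf hair formation, at 67.0 ± 7.48 against 283 ± 27.8 (-2.06 ± 0.21), AT5G12940 (-3.05 ± 0.55) and AT1G06260 (-2.73 ± 0.56). HSA32, needed for lasting heat tolerance, was lower by -1.08 ± 0.27 (adjusted p = 0.0256); the call ended without Col-0 high light replicate 2 (-0.94), Col-0 high light replicate 3 (-0.78) or WRKY40 overexpressor high light replicate 2 (-0.95). It also ended on only the arrays compared (adjusted p = 0.204). The heat shock list had a median of -0.31 with 1 of 6 members called and 2 when adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.064 with an estimated correlation; median -0.09 and adjusted p = 0.196 with quantile normalization, and -0.29 and adjusted p = 0.0643 without WRKY40 overexpressor high light replicate 1).

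Limma called 388 probe sets, 210 higher and 178 lower, a share of 54.1% higher that was 44% with quantile normalization. The count was 228 without Col-0 high light replicate 2, 188 and 242 without WRKY40 overexpressor high light replicates 2 and 3, and 131 on only the arrays compared. Of 13 named genes called, 6 lost the call when 1 array was left out. NDB2 (0.25 ± 0.21) and AT2G21640 (0.60 ± 0.29, adjusted p = 0.331) were not called. In both lights 101 probe sets were called in the same direction.

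The WRKY63 knockout after high light had 4 calls by limma, 1 higher and 3 lower, against 1321 probe sets at an unadjusted p under 0.05. The 3 that name 1 gene were QQS, a regulator of starch content, at 102 ± 32.8 against 849 ± 143 (-3.08 ± 0.51, adjusted p = 0.0166), AT1G76185 at 90.0 ± 10.1 against 173 ± 9.44 (-0.94 ± 0.16, adjusted p = 0.0166) and AT1G08940 at 17.2 ± 8.8 against 74.0 ± 8.0 (-2.19 ± 0.40, adjusted p = 0.0449). Each of these 3 calls was lost when 1 array was left out, with the highest adjusted p at 0.144 for QQS (-2.80) and AT1G76185 (-0.86) without WRKY63 knockout high light replicate 2 and 0.247 for AT1G08940 (-1.68) without replicate 1; leaving out any Col-0 high light array also ended all 3, with QQS at -3.19, -2.96 and -3.10. With a pseudocount of 16 AT1G08940 had -1.47 (adjusted p = 0.154), and on only the arrays compared AT1G76185 and AT1G08940 were not called (adjusted p = 0.153 and 0.218). The count was 2 and 1 without Col-0 high light replicates 1 and 3, and 1 and 10 without WRKY63 knockout high light replicates 2 and 3. NDB2 (-0.25 ± 0.21, adjusted p = 0.825) and AT2G21640 (0.01 ± 0.29, adjusted p = 0.998) were not called.

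In the WRKY63 overexpressor after high light WRKY53 was at 1770 ± 666 against 247 ± 64.1 (2.78 ± 0.42, adjusted p = 1.08e-04), and WRKY6 at 245 ± 144 against 53.9 ± 3.19 (2.02 ± 0.52, adjusted p = 0.0136). These are 2 of the 3 members, of 31 on the WRKY list, with a kept named probe set, also 2 when adjusted over the list alone. CYP71B23 (528 ± 303 against 41.3 ± 36.3), AT2G42360 (635 ± 136 against 36.5 ± 30.9), AT5G08240 (505 ± 345 against 25.0 ± 14.6) and ZCF37 (309 ± 49.4 against 24.1 ± 13.9) were higher, and so was SAG101, a defence gene, by 1.75 ± 0.31 (adjusted p = 0.0721 on only the arrays compared). AT1G66850 was lower, at 38.9 ± 38.0 against 436 ± 150 (-3.86 ± 0.62), as were AT5G22430 (67.2 ± 50.4 against 482 ± 154), AT1G68875 (11.3 ± 15.1 against 154 ± 57.1) and ATA27 (10.3 ± 7.72 against 163 ± 100), the last without a call on leaving out Col-0 high light replicate 1 (-3.57) or 2 (-3.93) or WRKY63 overexpressor high light replicate 1 (-3.20). With a pseudocount of 16 AT1G68875 had -2.71 and ATA27 -2.64, against -4.35 and -4.03. In the same groups a separate list of 7 anther and pollen coat genes had a median log2 difference of -1.38, and -0.68 without replicate 3 of this group, an array with a high actin ratio. WRKY6 had 1.57 (adjusted p = 0.0989) without that array.

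Limma called 1621 probe sets, 874 higher and 747 lower. The count was 868 without WRKY63 overexpressor high light replicate 3, 934 and 1046 without Col-0 high light replicates 1 and 2, 439 on only the arrays compared and 947 on the 28 arrays. Of the 439 calls 337 were higher and 102 lower, a share of 76.8% higher against 53.9%. NDB2 had 0.63 ± 0.21 (adjusted p = 0.0549; 0.047 with a pseudocount of 16, and 0.76 with 0.0489 without Col-0 high light replicate 2) and AT2G21640 0.18 ± 0.29. Autophagy genes of the ATG8 and ATG3 families, which build the autophagosome membrane, had 4 of 10 probe sets higher (camera adjusted p = 0.0049; adjusted p = 0.43 with an estimated correlation). In both lights 275 probe sets were called in the same direction, of which 138 were higher and 5 lower by at least 2-fold in each.

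The overexpressor and knockout of each gene were also set against each other over both lights. For WRKY40, AT1G66100 (8.72 ± 0.32), AT2G25510 (7.97 ± 0.15) and AT1G76960 (7.25 ± 0.39) were higher in the overexpressor, and AOP3 (-8.27 ± 0.47), AT5G55450 (-3.62 ± 0.34) and AT3G48640 (-3.56 ± 0.32) were lower. The overexpressor was not called against Col-0 in either light for these genes, as with AT2G25510 at 25100 ± 3420 against 31500 ± 5200 without treatment, except AT1G66100, which was lower in the untreated overexpressor at 1780 ± 1120 against 6540 ± 4590. For WRKY63, AT3G18250 (5.40 ± 0.60), AT2G42360 (4.64 ± 0.51) and AT1G13470 (4.13 ± 0.30) were higher in the overexpressor, and AT1G68875 (-4.01 ± 0.75, and -2.49 with a pseudocount of 16), ATA27 (-3.33 ± 0.85) and AT1G66850 (-2.64 ± 0.44) were lower. Limma called 4428 probe sets for WRKY40, 2222 of them higher in the overexpressor, and 3058 for WRKY63, 1489 of them higher.

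The lines share the Col-0 arrays, so their differences from Col-0 are correlated by chance: simulated unchanged groups gave a correlation of 0.50 and a covariance of 0.04, with 0 shared calls over 100 simulations. The simulation held no true changes and errors independent between probe sets. Its 0 shared calls therefore do not measure what the shared arrays add to the overlaps below. After high light the WRKY40 knockout and the WRKY63 overexpressor shared 238 probe sets higher and 156 lower, where independent lists would share 64.5 and 58.7, with a correlation of 0.27 and a covariance of 0.089. Without treatment 65 probe sets were lower in the WRKY40 overexpressor and higher in the WRKY63 overexpressor, where 9.9 would be expected, with a correlation of -0.12 and a covariance of -0.021. Among the named genes AT4G16260 was lower in the first (-4.05) and higher in the second (3.05), the latter without a call on leaving out Col-0 untreated replicate 3 (2.08, adjusted p = 0.127) or WRKY63 overexpressor untreated replicate 1 (2.97, adjusted p = 0.0749). The 3 Col-0 arrays of each light were too few to split into separate controls for each line, so part of an excess in the same direction may come from the shared controls.

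The interaction asks whether high light changed a transcript differently in a line than in Col-0. In the WRKY40 knockout AT1G02700 went from 37.2 to 2970, against 18.5 to 217 in Col-0 (2.82 ± 0.51, adjusted p = 0.0041), and AT5G18340 from 94.0 to 107, against 18.8 to 451 in Col-0 (-4.45 ± 0.78, adjusted p = 0.00337). In the WRKY40 overexpressor ZCF37 went from 11 ± 4.09 to 51.8 ± 8.27, against 228 ± 174 to 24.1 ± 13.9 in Col-0. This interaction was 5.24 ± 0.75 (adjusted p = 0.00384, and 0.0551 on only the arrays compared). In the WRKY40 knockout, WRKY63 knockout and WRKY63 overexpressor that of ZCF37 was 2.76, 2.3 and 2.49, without a call. All lines share the Col-0 arrays, so part of the 5.24 may come from those arrays. In the WRKY63 knockout AT5G51440 went from 4.52 ± 0.352 to 13900 ± 2810, against 52.5 ± 13.1 to 16600 ± 1030 (2.98 ± 0.41, adjusted p = 0.00236), a difference that was 1.45 (adjusted p = 0.0511) with a pseudocount of 16. In the WRKY63 overexpressor AT1G52560 went from 223 ± 47.5 to 15500 ± 1180, against 1.96 ± 1.7 to 10100 ± 1490 (-5.74 ± 0.88, adjusted p = 0.005), which was -3.10 with a pseudocount of 16. For AT5G51440 and AT1G52560 the interaction lies in the untreated levels.

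For the WRKY40 knockout limma called 164 probe sets in the interaction, 89 higher and 75 lower, and 104 and 108 without Col-0 high light replicates 2 and 3 and 109 without WRKY40 knockout high light replicate 3. For the WRKY63 knockout 18 were called, 9 higher and 9 lower, and 6 with quantile normalization, a share of 100% higher against 50%. Leaving out 1 array gave 1 to 13 calls: 3 without Col-0 untreated replicate 2, 1 without Col-0 high light replicate 1, 2 or 3 or WRKY63 knockout untreated replicate 1, 2 or 3 or high light replicate 1, 5 without WRKY63 knockout high light replicate 2 and 4 without replicate 3. Nuclear photosynthesis genes had a median of 0.33 in this interaction, with 0 of 30 members called (camera adjusted p = 1.2e-10, and 0.027 with an estimated correlation). None of the alternatives run ended the call with the preset correlation, and the estimated correlation was not used in them. The same list had -0.14 against Col-0 without treatment and 0.10 in high light in that line. The other untreated lines lay below the same Col-0 arrays too, so part of the 0.33 may come from those arrays.

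For the WRKY40 overexpressor 35 probe sets were called in the interaction, 33 higher and 2 lower. The count was 64 and 3 without Col-0 untreated replicates 1 and 2, 16 without WRKY40 overexpressor untreated replicate 3, 14 and 12 without Col-0 high light replicates 1 and 2, and 14 and 15 without WRKY40 overexpressor high light replicates 2 and 3. A fit to only the arrays compared called 0 by limma, against 1147 at an unadjusted p under 0.05. For the WRKY63 overexpressor 66 were called, 31 higher and 35 lower. The count was 35 without Col-0 untreated replicate 3, 9 and 21 without WRKY63 overexpressor untreated replicates 1 and 3, 37, 43 and 39 without Col-0 high light replicates 1, 2 and 3, and 158 and 39 without WRKY63 overexpressor high light replicates 2 and 3.

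**Figure D3:**
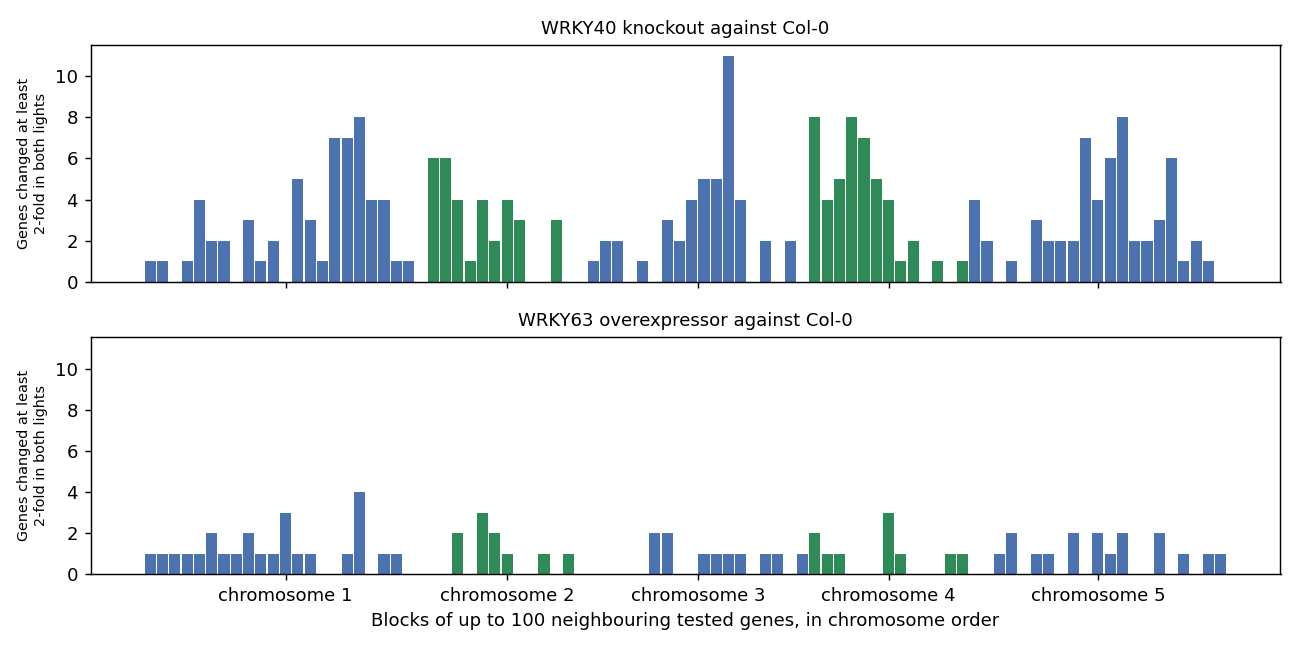
Number of genes changed at least 2-fold in both lights (linear axis) in each block of up to 100 neighbouring tested genes along the 5 chromosomes, for the WRKY40 knockout (top) and the WRKY63 overexpressor (bottom) against Col-0; colours alternate between chromosomes. The highest block held 11 genes in the WRKY40 knockout and 4 in the WRKY63 overexpressor.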

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

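The tests of the 3 patterns weighed here were chosen only after those results were seen; the counts over other splits of the arrays were planned before, and their breakdown by genotype difference and their repeats under other settings were added after. The bounds that decide the tests of the WRKY40 locus, of dim probe sets, of flower buds and of the array with the high actin ratio in the third pattern were set or rewritten with their values known.

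The response to high light differed from Col-0 by the interaction test for 164 probe sets in the WRKY40 knockout, 35 in the WRKY40 overexpressor, 18 in the WRKY63 knockout and 66 in the WRKY63 overexpressor. Other splits of the same arrays gave as many calls, the real split included, in 9, 6, 1 and 8 of 100 splits, with highest other counts of 1565, 309, 12 and 422. Each of the 8, 5 and 7 other splits that reached the count of the WRKY40 knockout and the 2 overexpressors puts part of the difference between genotypes into the interaction, a structure of the samples, so these splits do not decide on chance there. The drawn splits without such a part gave at most 0, 1, 12 and 3 calls, although mixing genotypes in a group also widens its spread. For the WRKY63 knockout the real split alone, 1 of 100, reached its count at the settings used here, a share under 0.05. With a pseudocount of 16, the 50th percentile filter, the replicate block, no variance trend or only the arrays compared, 1 to 3 of 100 splits reached the real count. With no filter or quantile normalization 5 of 100 did, with highest others of 10 and 11 against 5 and 6. The share thus depends on the settings, and chance is not excluded for this line. Its 18 calls were 6 with a pseudocount of 16, quantile normalization or no variance trend, 5 with no filter or the replicate block, 10 on only the arrays compared, 1 on the 28 arrays and 1 to 13 when 1 array was left out. Of its 6 named calls, AT3G05730, AT1G76185, AT5G25475 and AT1G72230 had an adjusted p of 0.0499.

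The genes named by the rule had these interaction values on the log2 scale. In the WRKY40 knockout AT5G59670 had 4.18, AT5G14730 4.08, AT5G37230 3.18, AT1G02700 2.82, AT3G28270 -2.66, AT1G64300 -3.23, AT3G28840 -4.04 and AT5G18340 -4.45. In the WRKY40 overexpressor ZCF37 had 5.24, AT4G00700 4.66, AT5G08240 3.99 and AT1G06260 -4.27. In the WRKY63 knockout AT4G39670 had 3.77, AT5G51440 2.98, AT3G05730 1.84, AT1G76185 -1.10, AT5G25475 -1.19 and AT1G72230 -1.94. In the WRKY63 overexpressor AT3G01830 had 3.02, AT4G01870 1.79, AT5G35735 1.62, CHR24 -2.57, AT4G31875 -3.22 and AT1G52560 -5.74. With a pseudocount of 16 AT1G64300 had -1.63, AT3G28840 -2.17, AT4G39670 2.47, AT5G51440 1.45 and AT1G52560 -3.10 in these interactions, without a call for AT3G28840, AT4G39670 and AT5G51440; AT5G08240, AT1G76185 and AT5G25475 lost their calls as well. On only the arrays compared there was no call for AT5G59670, AT5G37230, AT1G64300 and AT3G28840, for the 4 genes named in the WRKY40 overexpressor, for AT4G39670, AT1G76185 and AT5G25475, or for AT3G01830, AT4G01870 and AT4G31875. On the 28 arrays AT4G01870 had 1.16 (adjusted p = 0.216). Over all alternatives the calls of AT3G05730, AT1G76185, AT5G25475 and AT1G72230 ended in 17, 19, 19 and 18 of 20, and those of AT3G01830 and AT4G01870 in 11 of 20 each. Of 19 alternatives, AT4G00700 lost its call in 14, AT5G08240 in 13, AT4G39670 in 11, AT5G37230 in 10, AT5G59670 in 8, AT4G31875 in 6 and AT1G06260 in 5. AT5G14730, AT5G18340 and AT1G52560 lost it in 0, the remaining genes in 1 or 2, and AT1G02700 and AT3G28270, named through other comparisons, were not recomputed. Some named genes shared a sign in every line. In the WRKY40 knockout and overexpressor and the WRKY63 knockout and overexpressor AT4G39670 had 2.01, 2.97, 3.77 and 2.35. In that order AT3G01830 had 2.24, 3.12 (adjusted p = 0.037), 2.3 and 3.02, and AT1G06260 -2.49, -4.27, -2.46 and -2.2. Others did not, such as AT5G18340 (-4.45, 0.42, -0.65 and 0.52). The shared Col-0 arrays may account for part of the values with a common sign.

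The comparisons of 2 groups have 10 splits, too few for a share under 0.05, and in each the real split alone, 1 of 10, reached the real count. The highest count of the other splits was 4 against 6995 for high light in Col-0, 4 against 6898 in the WRKY40 knockout, 1 against 6507 in the WRKY40 overexpressor, 0 against 7399 in the WRKY63 knockout and 1 against 8152 in the WRKY63 overexpressor. Against untreated Col-0 it was 1 against 2271 for the WRKY40 knockout, 8 against 390 for its overexpressor, 23 against 80 for the WRKY63 knockout and 4 against 678 for its overexpressor. Against Col-0 in high light it was 3 against 2426, 8 against 388, 1 against 4 and 6 against 1621 in the same order. For overexpressor against knockout over both lights 1 of 100 splits, the real one, reached the real count, a share under 0.05. The highest others were 1906 against 4428 for WRKY40 and 1130 against 3058 for WRKY63, although mixing lines in a group also widens its spread. A random grouping of these arrays is thus unlikely. Since replicates may be technical, chance differences between the samples of the 2 lines are not excluded.

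The WRKY40 knockout differed at least 2-fold in both lights at 431 probe sets, and the 239 genes they name lay bunched along the chromosomes. With runs of neighbours merged the variance over the mean of the counts in 88 blocks of up to 100 neighbouring tested genes was 1.31, against a 95th percentile of 1.26 in 10000 random placements (permutation p = 0.032); 2 versions run after that gave 2.25 without merging (p = 1e-04, the smallest these resamples can give) and p = 0.001, again the smallest, with the random placements merged too. Draws of as many genes from those called for high light in Col-0 had a 95th percentile of 0.97. Random placements, merged too, had 0.96. Genes that WRKY40 regulates could bunch more than the genes drawn. The draws therefore do not decide on loss of WRKY40 activity alone, which stays open. Among the 100 tested genes nearest the WRKY40 locus 0 had changed against 2.79 expected, but 18 of the 88 blocks also hold 0 and random placements give 0 with a probability of 0.058, so a segment there stays open. Chromosome segments of another accession elsewhere stay open too as a hypothesis. AOP3, known to be expressed in leaves of Landsberg erecta and not of Col-0, was at 8490 against 32.6. AT2G25450, also picked as a marker between these accessions, was at 32.2 against 4940. Both genes were already named among the largest differences of this comparison, so they are no separate test of such segments. In the other untreated lines AOP3 was at 18.6 to 47 and AT2G25450 at 3580 to 4370. The 27 and 73 such genes of the WRKY40 and WRKY63 overexpressors, fewer than here, showed no bunching with neighbours merged (permutation p = 0.72 and 0.97). With the random placements merged too the permutation p was 0.54 and 0.92, and without merging it was 0.35 and 0.73.

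Mitochondrion-encoded transcripts had a median log2 change of 1.22 after high light in Col-0. With quantile normalization the list's median lay 1.48 above that of all probe sets, which argues against scaling. Without the 2 arrays with high actin ratios the list's median in Col-0 was 1.27. This argues against Col-0 untreated replicate 2 as the cause. The other array, from the WRKY63 overexpressor in high light, has no part in this median, so its effect was not tested here. Only 6 of the 18 probe sets lie above the 50th percentile of signal, and their median was 0.11, so a rise of dim probe sets alone, from transcripts or from background, stays open. A change of mitochondrial transcripts by high light stays open as well.

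In the WRKY63 overexpressor after high light ATA27, AT1G66850, AT1G68875 and AT5G22430, 4 genes picked as anther-type after their values were seen, were lower than in Col-0. Without replicate 3, the array with the high actin ratio, their median was -4.14 against -3.94 with it, but genes picked as among the largest falls decide nothing about that array. A separate list of anther and pollen coat genes, with mean log2 signals of only 3.63 to 5.49 against 3.79 to 7.26 in Col-0 and SDs up to 2.19, had a median of -1.38, but -0.68 without that array, so 1 array may account for much of this shift. In untreated plants, where no array of this line had a high actin ratio, the list median per array was 5.74, 4.21 and 5.54 against 6.63, 5.37 and 5.86 in Col-0. The 5.37 is from Col-0 untreated replicate 2, which itself has a high actin ratio (2.35). In high light 6 of 7 members were lower in the WRKY63 overexpressor, and AT1G75890 was higher by 1.03. The other lines lay below Col-0 in high light too, with 7 of 7 members lower in the WRKY63 knockout (median -0.57) and the WRKY40 overexpressor (-0.28) and 4 of 7 in the WRKY40 knockout (-0.41). The interactions of ATA27 in the WRKY40 knockout, WRKY40 overexpressor, WRKY63 knockout and WRKY63 overexpressor were -3.41, -4.24, -3.66 and -2.90. Those of AT1G66850 were -2.96, -3.74, -3.22 and -2.31, of AT1G68875 -2.44, -3.46, -2.28 and -1.98 and of AT5G22430 -0.94, -1.51, -2.03 and -2.50. None was called. All lines share the Col-0 arrays, which may account for part of these values. The separate list had 5.85, 5.39 and 5.54 in Col-0 after high light. That array, the Col-0 arrays, fewer flower buds among the leaves and an effect of WRKY63 on these genes all stay open.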

How the results depend on the processing

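The fit to the 28 arrays without high actin ratios was chosen after the data were seen; the other alternatives were planned. High light in each genotype, the WRKY40 knockout in high light and both comparisons of overexpressor with knockout stayed within 1.5 times their counts under every alternative run. Values printed here are counts of calls unless said otherwise, and the cause was not tested except where fewer arrays or probe sets show it.

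The interaction of the WRKY63 knockout had 18 calls, and 6 with a pseudocount of 16, 5 with no filter, 6 with quantile normalization, 6 without a variance trend, 10 on only the arrays compared and 1 on the 28 arrays. That of the WRKY40 overexpressor had 35, and 19 with no filter, 11 with the 50th percentile filter, 23 with quantile normalization, 0 on only the arrays compared and 10 on the 28 arrays. The WRKY63 knockout in high light had 4, and 2 with no filter, the 50th percentile filter or only the arrays compared. The 50th percentile filter, with fewer probe sets tested, left 108 of 189 called named genes. On only the arrays compared, with fewer arrays to estimate the spread, the counts were 1373, 239 and 17 for the untreated WRKY40 knockout, WRKY40 overexpressor and WRKY63 knockout, 131 and 439 for the WRKY40 and WRKY63 overexpressors in high light, and 104 and 9 for the interactions of the WRKY40 knockout and WRKY63 overexpressor. On the 28 arrays they were 247 and 4 for the untreated WRKY40 overexpressor and WRKY63 knockout, 947 for the WRKY63 overexpressor in high light and 26 for its interaction.

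Leaving out 1 array gave 5853 to 6625 calls for high light in Col-0, 5892 to 6320 in the WRKY40 knockout, 5424 to 6365 in its overexpressor, 6384 to 6694 in the WRKY63 knockout and 7156 to 7631 in its overexpressor. Against untreated Col-0 the ranges were 1531 to 1991, 218 to 417, 6 to 111 and 308 to 592, against Col-0 in high light 1783 to 2059, 188 to 532, 1 to 10 and 868 to 1658, and for the interactions 104 to 194, 3 to 64, 1 to 13 and 9 to 158. Overexpressor against knockout gave 3835 to 4387 for WRKY40 and 2459 to 3135 for WRKY63, list tests 58 to 70 and called named genes 162 to 186. The overlap of calls between lines was not recomputed on fewer arrays.

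Replicate numbers did not pair the samples by the rule used: in 0 of 13 comparisons were all 3 correlations of same-numbered arrays over 0.1 (range -0.13 to 0.32). In the same light the mean correlation was 0.084 for same-numbered arrays and -0.042 for other numbers. The second value adds little to the first, as deviations from a group mean cancel out within the group. Between the lines and Col-0 the correlations of same-numbered arrays ran from 0.01 to 0.32 in high light and from -0.12 to 0.27 without treatment. A shared replicate effect is thus not excluded. With the replicate block high light in Col-0 had 7106 calls, the interaction of the WRKY63 knockout had 5, and the other counts stayed within 1.5 times.

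Directions turned only for values without a call. For the heat shock list the direction of camera's test turned from down to up, while the median mostly kept its sign. With quantile normalization the median was -0.01, against -0.09, for the WRKY40 knockout in high light and 0.04, against -0.11, for the WRKY63 overexpressor in high light. When 1 array was left out it was 0.09 and 0.08, against 0.09, for the untreated WRKY40 overexpressor (lowest -0.07), 0.02, against 0.07, for the untreated WRKY63 knockout (range -0.20 to 0.12), and -0.09, -0.01 and -0.09, against -0.11, for the WRKY63 overexpressor in high light. In both untreated lines the median with all arrays was above 0 and the test direction down. The value of AT2G21640 changed sign: it turned to 0.21 (also on the 28 arrays) and 0.03 in the untreated WRKY40 knockout (lowest -0.56), 0.01 (also on the 28 arrays) in the untreated WRKY63 overexpressor (lowest -0.76), -0.24 in the untreated WRKY40 overexpressor (highest 0.53) and -0.26 in the untreated WRKY63 knockout (highest 0.51). In high light it turned to -0.17 and -0.13 in the WRKY63 knockout (highest 0.13) and 0.00 in the WRKY63 overexpressor (highest 0.33). Of 203 named gene values, leaving out 1 array ended the call in 250 of 1422 refits and made 2, and a fit to only the arrays compared ended 49.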

Other observations

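Of 30 probe sets in the list of nuclear photosynthesis genes, 1 was higher and 13 were lower in Col-0 after high light, with a median log2 change of -0.27, and the list was not called (camera adjusted p = 0.11, and adjusted p = 0.63 with an estimated correlation). Among its members PORB, a protochlorophyllide reductase, fell by 1.69 ± 0.14 on the log2 scale (limma adjusted p = 1.8e-10), PIFI by 0.81 ± 0.11, CHLM by 0.75 ± 0.11 and LIL3:2 by 0.70 ± 0.10, while PGRL1B rose by 0.53 ± 0.16 (adjusted p = 0.01). RCA (0.20 ± 0.12, adjusted p = 0.17) and PSAN (-0.08 ± 0.10, adjusted p = 0.57) were not called. Of 7 tubulins 5 were lower, without a call for the list (camera adjusted p = 0.09, and adjusted p = 0.48 with an estimated correlation): TUB5 fell by 2.62 ± 0.13 and TUA1 had 0.05 ± 0.13.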
